A study of Mus musculus with 4 samples.

How the data were processed

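Ribosome footprints were sequenced from mouse ESCs and EBs, WT and Mettl3-KO, 1 library of each. Per the labels' protocols, lysates were digested with RNase I, ribosomes were pelleted through a sucrose cushion, and the protected fragments were size-selected on gels, ligated, reverse transcribed, circularised and amplified by PCR. Each library took its group from its own title, which names the genotype and the culture, and the columns of the deposited table were matched to the libraries by those names; 0 columns stayed unmatched. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie, TopHat2 2.0.10, HTSeq 0.6.0 and DESeq were used on build mm10. The settings, the annotation version and the treatment of strand are not given in the sources used here.

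The deposited values are a normalised signal per RefSeq coding sequence, which the authors made from read counts by dividing each library by 1 factor. They had been assumed to be normalised counts on which no count model could be run. In each library 100% of values were whole multiples of the library's smallest step within a tolerance of 0.01, so the read counts were recovered, and the median-of-ratios factors of DESeq, recomputed over all entries, matched the deposited ones. The main comparisons stayed on the deposited values, and a count test on the recovered reads was added. By edgeR that test called 20 genes higher and 5 lower in EBs than in ESCs, and 0 between KO and WT, where 1556 had an unadjusted p under 0.05 and DESeq2 called 251 higher and 71 lower.

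The table holds 27442 coding sequences and 5 summary entries that name no gene. A reference table of assembly GRCm38.p6, the same assembly as mm10, gave symbols and positions for 27083 sequences. The other 359 held at most 0.422% of a library's gene reads, and each was kept as a gene of its own. Sequences of a gene were summed to 20716 genes, of which 14376 had a read. The reads in the table numbered 30677431 in WT ESCs, 34316894 in KO ESCs, 13520720 in WT EBs and 14369037 in KO EBs. Genes held 27.9%, 33.4%, 31.3% and 28.4% of them in that order. Reads without a unique place made up 55.7%, 48.4%, 51.7% and 53.1%, ambiguous reads 8.71%, 10.5%, 9.74% and 8.62%, and reads on no feature 7.70%, 7.70%, 7.25% and 9.88%. These entries stayed out of library sizes and tests. The 10 highest genes held between 1.85% and 2.70% of gene reads.

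This counting affects some genes more than others. No read was found for 21.9% of the 16833 genes with 1 coding sequence entry, against 68.3% of the 3883 genes with 2 or more entries, whose shared stretches count as ambiguous. Near-identical copies lose reads as not unique. Every 28-nt window of each coding sequence was therefore searched in both strands of the GRCm38.p6 genome, and the percent of windows with a copy elsewhere was taken as a measure of that loss; 38 tested genes had every window copied and 8272 of 9597 with windows had under 10%.

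Genes with a mean of at least 25 over the 4 libraries were compared, 9670 in all. With 1 library per group no p-value was computed for a comparison of 2 libraries: the log2 fold was taken with a pseudocount of 1, a gene counted when at least 2-fold apart, and the ratio of recovered reads had a 95% conditional exact binomial (Clopper-Pearson) interval. The difference between the EB changes of KO and WT counted at 1 or more on the log2 scale. A library at 0 was set to a floor of 3 reads per library to give a bound.

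Gene lists covered m6A factors, naive, general and formative pluripotency, primitive and visceral endoderm, mesoderm, heart and muscle, neural genes, fibroblast and extracellular matrix genes, blood, endothelium, trophoblast and simple epithelium, germline, the 2-cell-like state, cell cycle, glycolysis and hypoxia, cholesterol synthesis, the ATF4 response, p53 targets, interferon response, Wnt, ERK, and LIF and STAT3 targets, imprinted and Y-linked genes, ribosomal proteins, translation factors, oxidative phosphorylation and histones. The list of mitochondrially encoded genes had no measured member. In some lists few members passed the filter. Those passing were 7 of 26 heart and muscle, 8 of 23 mesoderm, 4 of 23 blood and 11 of 26 neural genes. Counts out of a list are out of the members that passed. Each list median was placed among 10000 random lists of the same size matched on mean expression in 10 bins. List medians were also taken without the pseudocount and with libraries at 0 set to their floor. This moved a list median by at most 0.885, and by over 0.1 only for Y-linked genes.

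The genes named were Mettl3, the 6 highest and 6 lowest genes of each comparison with a larger value of at least 100 (at least 200 over the 4 libraries for the difference), skipping unnamed gene models, and up to 4 members of each list, the 2 highest and 2 lowest. Some genes that this rule takes are not reported here. Groups, comparisons, lists, the naming rule, the filter, the pseudocount and the alternatives of pseudocount, filter and scaling were chosen before the data were examined.

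The added count test was edgeR's quasi-likelihood test with genotype and stage as additive terms, which leaves 1 residual degree of freedom, and DESeq2's Wald test with the same terms. Both used Benjamini-Hochberg adjustment. Both take the genotype-by-stage difference as noise. The procedures were tested on simulated data for 9670 genes. For KO against WT over both stages edgeR recovered 64% of 100 genes changed 4-fold and 11% of 100 changed 2-fold, and called 2 unchanged genes. The 2-fold rule recovered 100% of genes changed by 2 on the log2 scale in each comparison of 2 libraries. Of genes changed by 1.5 it recovered 98% for KO against WT in ESCs and 96% in EBs. For EBs against ESCs it recovered 97% in WT and 99% in KO. In that order 0, 21, 11 and 9 unchanged genes passed it. The spread between replicate libraries cannot be learned from 1 library per group. These counts therefore do not show how many unchanged genes pass the rule in the real data.

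Alternatives were pseudocounts of 10 and 0.5, no filter, a mean of at least 100 (at least 10 for correlations), equal totals, equal upper quartiles and a median log2 ratio of 0. Added after seeing the data were genes with 1 coding sequence alone, genes with under 10% of windows copied, thinning to the shallowest library, a 2-fold rule joined to the interval, factors from gene entries alone, and both count tests. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Matched RNA-seq was not used here, so footprint counts were not divided by mRNA levels.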

Results

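Ribosome profiling sequences the short mRNA stretches that translating ribosomes protect from nuclease, so that a gene's footprint count follows both the amount of its mRNA and how densely ribosomes occupy it. Footprints were collected from mouse embryonic stem cells (ESCs) and from embryoid bodies (EBs), the suspended aggregates in which such cells differentiate, on a C57BL/6 background. At each stage there was 1 library from wild-type (WT) cells and 1 from Mettl3 knockout (KO) cells. Mettl3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. The ESCs were kept naive in serum-free medium with LIF and inhibitors of GSK3 and MEK, and the EBs grew in serum-containing medium for 8 to 21 days; the day of each EB library is not given in the sources used here. The 4 libraries had no replicates, so no difference between them had a replicate check. Reads on coding sequences numbered 8570204 in WT ESCs, 11455539 in KO ESCs, 4234361 in WT EBs and 4075850 in KO EBs. After the authors' normalisation 1 read was worth 0.778, 0.533, 1.56 and 1.49 in the same order, and a floor of 3 reads per library corresponded to 2.34, 1.60, 4.68 and 4.48. Intervals are 95% counting intervals of the ratio of 2 libraries, and they and the floors cover counting error only. Log2 folds are of value + 1, which understates the change of low genes.

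Mettl3 (NM_019721; chromosome 14, 52294841 to 52308741 in GRCm38) had a normalised count of 563 in WT ESCs, 298 in KO ESCs, 429 in WT EBs and 327 in KO EBs, from 723, 558, 275 and 219 reads. It was 1.89-fold lower in KO ESCs than in WT ESCs (interval 1.69 to 2.12) and 1.31-fold lower in KO EBs than in WT EBs (1.09 to 1.57). The sources used here do not say which part of the gene was altered, and counts summed over the whole coding sequence cannot show a small deletion. The remaining footprints therefore give no check of the knockout, and the groups carry the names the labels give them.

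The first comparison set KO ESCs against WT ESCs, both naive. With 1 library of each, loss of Mettl3 cannot be told apart from a difference between the cell lines or libraries. Extracellular matrix genes stood higher in the KO library: 15 of 22 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 fold of 1.56. Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), stood at 31.9 in WT and 265 in KO, 8.29-fold higher (6.02 to 11.7), and Thbs1, the secreted glycoprotein thrombospondin, was 6.29-fold higher (5.31 to 7.50). Genes of trophoblast and simple epithelium were also higher, 8 of 11 by 2-fold or more with a median of 1.42, and 1 (Epcam, 2.46-fold, 2.29 to 2.65) was lower. They included the transcription factors Gata3 (41.3 and 265, 6.41-fold, 4.83 to 8.68) and Ascl2 (24.9 and 158, 6.34-fold, 4.39 to 9.44). Ascl2 is also on the list of Wnt targets. Of the 16 trophoblast and simple epithelium genes in the data, Cdx2, Elf5, Tpbpa, Prl3d1 and Cldn7 did not pass the filter. This list is called trophoblast or epithelial genes below. Naive pluripotency genes were lower in KO ESCs, with 4 of 14 at least 2-fold lower, 0 at least 2-fold higher and a median of −0.58.

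Among the naive genes the nuclear receptor Nr0b1 stood at 4198 in WT and 1569.9 in KO, 2.67-fold lower (2.56 to 2.80), and Dppa3 was 3.37-fold lower (2.78 to 4.10), although 65.3% of the Dppa3 coding sequence has a copy elsewhere in the genome. Klf2 went the other way, 1.54-fold higher (1.49 to 1.60). General pluripotency genes had a median of −0.46, with 3 of 12 at least 2-fold lower and 0 higher, and of −0.22 over the 6 of 12 with under 10% copied. Their members Lin28a, an RNA-binding protein of undifferentiated cells, and Utf1, a chromatin protein of pluripotent cells, differed by log2 folds of −1.32 and 0.82. Germline genes had a median of −0.58, with 6 of 15 at least 2-fold lower and 2 at least 2-fold higher. Lower were Sycp1 of the synaptonemal complex (860.1 and 73.6; 11.7-fold, 9.78 to 14.0), with 19.1% copied, and the piRNA factor Mael (5.14-fold, 4.02 to 6.63). Higher were Tdrd9 (14.8 and 42.7; 2.89-fold, 1.73 to 5.04) and Tex101 (17.9 and 41.6; 2.32-fold, 1.44 to 3.88). All of the 21 genes of the ATF4 and amino acid response stayed within 2-fold, yet 19 were below 0 and their median was −0.56. Asparagine synthetase, Asns, was 1.76-fold lower (1.72 to 1.798), and Atf4 itself 1.72-fold lower (1.63 to 1.81). Mesoderm genes had a median of 0.92, with 4 of 8 at least 2-fold higher and 0 lower, among them Snai1 (4.39-fold, 3.19 to 6.18). The interferon response had a median of 0.54, with 4 of 14 at least 2-fold higher and 0 lower, led by Oasl1 (52.9 and 348; 6.58-fold, 5.12 to 8.58).

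Of 9670 genes tested, 1024 were at least 2-fold higher and 427 at least 2-fold lower in KO ESCs. Among named genes with a value of at least 100 in either library, those at the upper end were Kdm5d, a Y-linked histone demethylase (1.56 and 211; 136-fold, 37.3 to 1124), Lingo3 (21.8-fold, 11.3 to 48.1), Irs3 (21.5-fold, 9.68 to 59.3), the elastic-fibre protein Fbln5 (17.0-fold, 12.9 to 22.8), Grrp1 and Tmem266. At the lower end, within the same limit, they included Dcaf8l on the X chromosome (378 and 11.7; 32.2-fold lower, 21.0 to 51.9), Map7d3, Ube2dnl1 (33.6% copied), Eppk1 and Sycp1. Among m6A factors the median was 0.23, above 9948 of 10000 random lists matched on expression, and the nuclear m6A reader Ythdc1 was 2.11-fold higher (2.00 to 2.23). Percentiles among random lists describe these libraries and are not tests of the condition. The 4 Y-linked genes tested had a median of 2.15, above 9997 random lists, and Ddx3y was 5.89-fold (4.93 to 7.10) and Uty 3.42-fold higher (2.67 to 4.42). Against such lists the medians of matrix and trophoblast genes lay above all 10000, that of naive genes above 3 and that of the ATF4 response above 0. Those of ribosomal proteins (−0.62, 60 of 62 below 0), histones (−0.41, 51 of 55) and oxidative phosphorylation (−0.35, 62 of 64) also lay above 0 of 10000. Most coding sequence of ribosomal proteins and histones is copied elsewhere in the genome. The 32 oxidative phosphorylation genes with under 10% copied had a median of −0.36.

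The second comparison set KO EBs against WT EBs, with the same limit. Of 28 primitive and visceral endoderm genes, 25 were at least 2-fold lower in KO EBs and 0 at least 2-fold higher, with a median log2 fold of −3.37, below all 10000 random lists. Transthyretin, Ttr, a thyroid hormone carrier made by visceral endoderm, stood at 1612 in WT EBs and 26.9 in KO EBs, 60.0-fold lower (37.8 to 102). Cubilin, Cubn, the endocytic receptor of that tissue (chromosome 2, 13276338 to 13491876), stood at 15999.9 and 331, 48.3-fold lower (42.3 to 55.4). Matrix genes were again higher in KO, 15 of 22 by 2-fold or more and 2 lower, with a median of 1.95. Naive pluripotency genes were higher as well, 4 of 14 by 2-fold or more and 1 lower, with a median of 0.37.

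The named endoderm genes nearest to equal were the laminin chain Lamc1, 1.40-fold lower in KO EBs (1.36 to 1.44), and apolipoprotein E, Apoe, 1.18-fold higher (1.15 to 1.22). Among named genes with a value of at least 100 in either library, those lowest in KO EBs included Spp2 (368 in WT and 0 in KO, at least 82.1-fold lower), the protease Habp2 (at least 78.0-fold lower), Ankrd1 (at least 38.3-fold lower), Gkn2 (at least 26.1-fold lower) and the aminopeptidase Enpep (137-fold lower, 37.5 to 1135). The highest within that limit were Rpl21, Tmem35a, the growth factor Pdgfc (17.1 and 670.2; 39.1-fold, 21.6 to 78.9), Tmem266, Napsa and Prrt3. For Rpl21, at 3.12 and 161, every 28-nt stretch of the coding sequence has a copy elsewhere in the genome.

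In the matrix list Col6a1, a collagen VI chain (chromosome 10, 76708792 to 76726044), stood at 109 in WT EBs and 1964 in KO EBs, 18.0-fold higher (14.2 to 23.2), and Col3a1 at 62.3 and 1094, 17.6-fold higher (12.8 to 24.8). Contractile members of the list were lower in KO EBs: smooth-muscle actin Acta2 2.93-fold (2.20 to 3.94) and Tagln 2.91-fold (2.20 to 3.88). The reprogramming factor Klf4 (chromosome 4, 55527137 to 55532475) stood at 243 and 1088, 4.48-fold higher in KO EBs (3.76 to 5.36), and Fgf4 was 2.80-fold higher (2.53 to 3.10). Dppa3 was lower, as in ESCs (3.17-fold, 2.49 to 4.07). Pou5f1, the core pluripotency factor Oct4, was 2.15-fold higher (1.99 to 2.32) with 25.3% of its sequence copied, in a list of general pluripotency genes with a median of 0.11 (0.34 over the 6 with under 10% copied). Formative and primed genes split, with 6 of 13 at least 2-fold higher, such as Sall3 (6.21-fold, 4.06 to 9.87), and 3 at least 2-fold lower, such as the tight-junction gene Cldn6 (4.21-fold lower, 3.79 to 4.68).

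ATF4-response genes were higher in KO EBs, 8 of 21 by 2-fold or more and 1 lower, with a median of 0.69; Atf5 stood at 59.2 in WT and 309 in KO (5.22-fold, 3.68 to 7.58) and Cebpb was 4.58-fold higher (4.02 to 5.24). Mesoderm genes had a median of 1.41, with 4 of 8 at least 2-fold higher and 0 lower (Twist1 9.71-fold higher, 5.60 to 18.2). Wnt targets had a median of 1.19, with 5 of 8 at least 2-fold higher and 1 lower (Ascl2 7.41-fold higher, 5.42 to 10.3). Of 26 heart and muscle genes 7 passed the filter, with a median of −0.85. Of these 3 were at least 2-fold lower, 0 at least 2-fold higher and 2 above 0. Myl9 was 5.48-fold lower (4.01 to 7.63) and Myl3 4.48-fold lower (3.22 to 6.34). Ribosomal protein genes had a median of 0.60, with 26 of 62 at least 2-fold higher and 0 lower, but their median member has 95.9% of its coding sequence copied elsewhere in the genome, and reads with no unique place were left out of the deposited counts. Over all genes 1469 were at least 2-fold higher and 1177 at least 2-fold lower in KO EBs. With each library scaled to the same total, the median of all genes moved by 0.117 in this comparison and by 0.125 in ESCs.

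Genes at least 2-fold higher in KO at both stages numbered 546, against 156 for independent lists of these sizes, and 149 were lower at both, against 52.0. Opposite directions were found for 80 genes that were higher in KO ESCs and lower in KO EBs, against 125, and for 67 the other way, against 64.9. The KO differences in ESCs and in EBs, which share no library, correlated across genes with a Spearman coefficient of 0.394 and a Pearson coefficient of 0.390; genes are not independent replicates, and 2 such correlations were computed.

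The third comparison followed WT cells from ESCs to EBs. Of the visceral endoderm genes 25 of 28 were at least 2-fold higher in WT EBs and 0 lower. Their median log2 fold was 5.22, or 5.31 with no pseudocount and libraries at 0 set to their floor. Ttr had 0 reads in WT ESCs and a count of 1612 in WT EBs, at least 690.2-fold higher. Apolipoprotein A1, Apoa1 (chromosome 9, 46228630 to 46230469), stood at 3.11 and 3116, 1001-fold higher (390.2 to 3676), apolipoprotein B, Apob, at 17.1 and 12038, 703-fold higher (464 to 1122), and alpha-fetoprotein, Afp, at 17.9 and 8637, 482-fold higher (321 to 762). Naive pluripotency genes were lower, 13 of 14 below 0 and 5 at least 2-fold lower with a median of −0.89 (−1.36 over the 10 with under 10% copied), and Klf4 stood at 2371 and 243, 9.75-fold lower (8.30 to 11.5).

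**Figure D1:**
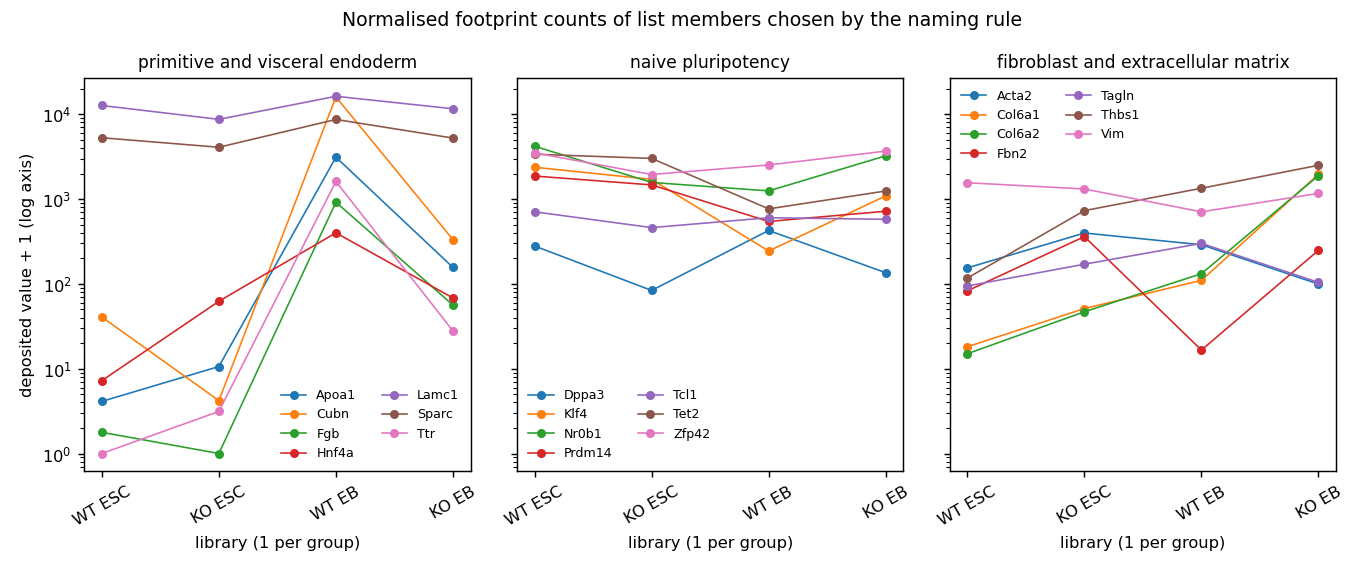
Deposited normalised footprint count plus 1 (log axis) of members chosen by the naming rule in the endoderm, naive pluripotency and extracellular matrix lists, with 1 point per library and a line joining the 4 libraries of a gene. Ttr and Cubn stood at 1612 and 15999.9 in WT EBs against 26.9 and 331 in KO EBs, Klf4 at 243 against 1088 and Col6a1 at 109 against 1964.

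The fibrinogen chain Fgb stood at 0.778, a single read, in WT ESCs and 918 in WT EBs (1179-fold, 211 to 46662), and the carbonic anhydrase Car4 at 3.89 and 3761 (966-fold, 414 to 2979). Epithelial genes had a median of 2.91, with 9 of 11 at least 2-fold higher and 0 lower; the 9 members with under 10% of their sequence copied elsewhere had 1.46. The keratin Krt18, with 17.3% copied, was 27.3-fold higher (23.4 to 32.2). ERK targets, transcribed in response to the kinase cascade that MEK belongs to, had a median of 1.61 with 9 of 14 at least 2-fold higher and 0 lower. The phosphatase Dusp4 was 22.1-fold higher (17.3 to 28.6). Matrix genes had a median of 1.498, with 12 of 22 at least 2-fold higher and 2 lower (Thbs1, 11.6-fold higher, 9.70 to 13.8). Mesoderm genes had 1.35, with 5 of 8 higher and 2 lower (Snai1, 12.0-fold higher, 8.71 to 16.9). The endothelium median was 0.81, with 4 of 9 higher and 1 lower (the VEGF receptor Flt1, 30.2-fold higher, 19.98 to 47.8), which reversed to −0.75 over members with a mean of at least 100. For heart and muscle the median was 0.42, with 3 of 7 higher and 1 lower (Myl3, 129-fold higher, 43.4 to 630.1). Formative genes had a median of 0.39, with 6 of 13 at least 2-fold higher and 2 lower. The Nodal antagonist Lefty1, with 39.1% of its sequence copied, was 7.02-fold higher (5.57 to 8.91). Glycolysis and hypoxia genes had a median of 0.41, with 5 of 18 at least 2-fold higher and 0 lower, led by the prolyl hydroxylase P4ha1 (4.39-fold, 4.10 to 4.70).

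Lower in WT EBs were the DNA demethylation enzyme Tet2 (4.42-fold, 4.02 to 4.86), the ATF4 response (median −0.76, 7 of 21 at least 2-fold lower and 0 higher; Atf5 4.17-fold, 2.97 to 6.00) and neural genes (median −0.68, 5 of 11 at least 2-fold lower and 0 higher; Nes 2.94-fold, 2.31 to 3.78). Wnt targets, genes of the pathway that GSK3 restrains, split, with 2 of 8 at least 2-fold higher, 2 at least 2-fold lower and a median of −0.50. Cdx1 stood at 269 and at a single read (173-fold lower, 30.8 to 6844) and Notum was 11.3-fold lower (8.28 to 15.8). Follistatin, Fst, was 3.01-fold higher (2.49 to 3.65) and Ascl2 2.82-fold higher (1.75 to 4.58). With a value of at least 100 in either library, the other named genes at the lower end were Ube2dnl1 (at least 27.8-fold), Klhl34 (at least 24.5-fold), Dcaf8l (121-fold, 33.4 to 1005), Accsl (113-fold, 20.1 to 4497) and Dmgdh (70.6-fold, 23.99 to 344). Utf1 and Lin28a, by contrast, were 4.05-fold (3.81 to 4.30) and 4.44-fold (3.91 to 5.05) higher in WT EBs. In all 1061 genes were at least 2-fold higher and 798 at least 2-fold lower, and 436 and 276 passed 4-fold.

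The fourth comparison followed KO cells from ESCs to EBs. With a value of at least 100 in either library, the named genes highest in KO EBs included Col15a1, a basement-membrane collagen, at 1.60 and 400.0 (250.0-fold, 84.6 to 1219.8), matrix Gla protein, Mgp, at 13.9 and 1185 (85.5-fold, 57.9 to 132), and the BMP antagonist Grem1 at 14.9 and 719 (48.2-fold, 32.9 to 73.3). Of the 22 genes of the matrix list 15 were at least 2-fold higher and 1 lower, with a median of 1.24, and Col6a1 stood at 50.1 and 1964 (39.2-fold, 31.8 to 48.8). Endoderm genes were higher in KO EBs than in KO ESCs too, 20 of 28 by 2-fold or more and 1 lower, with a median of 1.57 in KO and 5.22 in WT. Naive pluripotency genes had a median of −0.05, negative with equal totals too and above 0 with equal upper quartiles or a median log2 ratio of 0, and of −0.40 over the 10 members with under 10% copied, with 1 of 14 at least 2-fold higher (Nr0b1, 2.06-fold, 1.95 to 2.18) and 2 at least 2-fold lower (Tet2, 2.42-fold lower, 2.25 to 2.61, and Prdm14, 2.05-fold lower, 1.86 to 2.26).

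Cubn stood at 3.20 in KO ESCs and 331 in KO EBs (104-fold higher, 46.8 to 285), Fgb at 0 and 55.2 (at least 34.5-fold higher) and Car4 at 2.13 and 129.9 (60.9-fold higher, 22.9 to 228). Formative genes had a median of 1.07 with 7 of 13 at least 2-fold higher and 1 lower. Lefty1 was 13.1-fold higher (11.3 to 15.3) and Lefty2 6.60-fold higher (5.87 to 7.43), each with 39.1% of its sequence copied elsewhere. General pluripotency genes had a median of 0.45, mesoderm 1.17 (Hand1, 13.3-fold, 9.51 to 19.1), endothelium 1.24 (Plvap, 34.5-fold, 10.9 to 175), which reversed to −0.34 over members with a mean of at least 100, epithelium 1.65 (Krt19, 6.06-fold, 5.11 to 7.21) and ERK targets 1.28 (the immediate-early gene Egr1, 53.9-fold, 26.7 to 127). The p53 targets had a median of 0.60, with the pro-apoptotic Bbc3 2.75-fold higher (2.27 to 3.33). Imprinted genes had a median of 0.76, with the cell-cycle inhibitor Cdkn1c 5.11-fold higher (3.00 to 8.90). The 14 imprinted members counted include Nckap1, which was matched through a synonym and was not in the list as chosen. Neural genes had a median of −0.68, as in WT, and Sox1 was 19.5-fold lower (5.26 to 163).

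Within the same limit the genes at the lower end included all 4 Y-linked genes tested, Kdm5d (211 and 0, at least 47.2-fold lower), Eif2s3y (435 and 4.48; 97.1-fold lower, 33.1 to 472), Uty (15.4-fold lower, 8.05 to 34.0) and Ddx3y (12.6-fold lower, 8.90 to 18.4), then the deiodinase Dio3 and Spic. The Y-linked median was −5.08 in KO and −4.48 in WT. With no pseudocount and libraries at 0 set to their floor it was −4.75 and −3.59. In all 900 genes were at least 2-fold higher and 643 at least 2-fold lower. Genes higher in EBs of both genotypes numbered 428, against 98.7 for independent lists, and 201 were lower in both, against 53.1. The changes of WT and KO, which share no library, correlated across genes with a Spearman coefficient of 0.276 and a Pearson coefficient of 0.448.

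**Figure D2:**
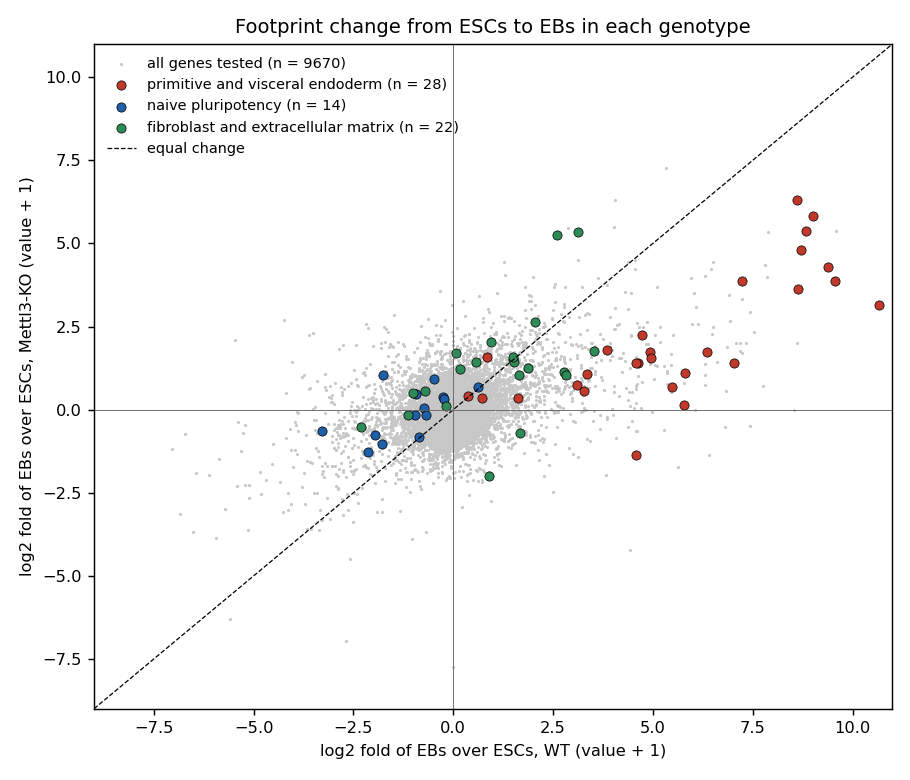
The log2 fold of EBs over ESCs (value + 1) in WT cells on the horizontal axis and in KO cells on the vertical axis, 1 point per gene for 9670 genes, with 3 gene lists in colour and equal change as a dashed line. The 28 endoderm genes have a median of 5.22 in WT and 1.57 in KO, and the 14 naive pluripotency genes medians of −0.89 and −0.05, the latter above 0 with equal upper quartiles or a median log2 ratio of 0 but not with equal totals.

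The last comparison set the EB change of KO cells against that of WT cells, as the difference of the log2 folds over all 4 libraries. For visceral endoderm the change was smaller in KO cells, with 25 of 28 genes lower by at least 1, a median difference of −3.30 and Ttr at −7.50. Among named genes with a value of at least 200 in any library, the others with the lowest differences were Spp2 (−8.53), Muc13 (−7.92), Habp2 (−7.79), the Y-linked Kdm5d (−7.73) and the FGF co-receptor Klb (−7.36). Spp2, Habp2 and Kdm5d had 0 reads in KO EBs, and Spp2 and Ttr had 0 in WT ESCs. The differences and ranks of these genes therefore depend on the pseudocount. Naive pluripotency genes had all 14 differences above 0 and a median of 0.80: Nr0b1 differed by 2.79, being lower in EBs in WT and higher in KO, and Klf4 by 2.63. The ATF4 response differed by a median of 1.25, with 12 of 21 genes at least 1 higher and 1 at least 1 lower, among the former the cystine transporter Slc7a11 (2.48) and Atf5 (2.36). Epithelial genes had lower differences (median −0.73, or −0.45 over the 9 with under 10% copied; Krt8 −2.43, with 71.2% of its sequence copied elsewhere), and Acta2 and Tagln differed by −2.91 and −2.38 while Col6a1 and Col6a2 differed by 2.66 and 2.20.

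Within the same limit the highest differences belonged to Cdx1 (5.99), to Rpl5 (5.85) and Rpsa (5.81), whose whole coding sequences are copied elsewhere, and to the complement regulator Cfp (4.77), the inhibin chain Inhbb (4.69) and Kbtbd11 (4.67). Of 9670 genes 1103 differed by at least 1 upward and 1205 downward, but 1300 and 1010 with equal upper quartiles and 1191 and 1111 with a median log2 ratio of 0, so which direction held more genes depends on the scaling. Other lists with a median outside the middle of their random lists included formative genes at 0.73, which split, with 5 of 13 at least 1 higher and 5 at least 1 lower (Lefty2 at 3.35 and Car2 at −2.25). Mesoderm stood at 1.17, with 5 of 8 at least 1 higher and 2 lower, and matrix at 0.43, with 8 of 22 at least 1 higher and 5 lower. The others were general pluripotency (0.61, or 0.39 over the 6 with under 10% copied, with Pou5f1 at 1.68), p53 targets (0.56), the 2-cell-like state (1.29), oxidative phosphorylation (0.36), histones (1.10) and ribosomal proteins (1.11). In the last 2 most coding sequence is copied elsewhere in the genome, and the 4 histone genes with under 10% copied had a median of 1.02. Equal upper quartiles moved the median of all genes by 0.114 in this comparison.

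**Figure D3:**
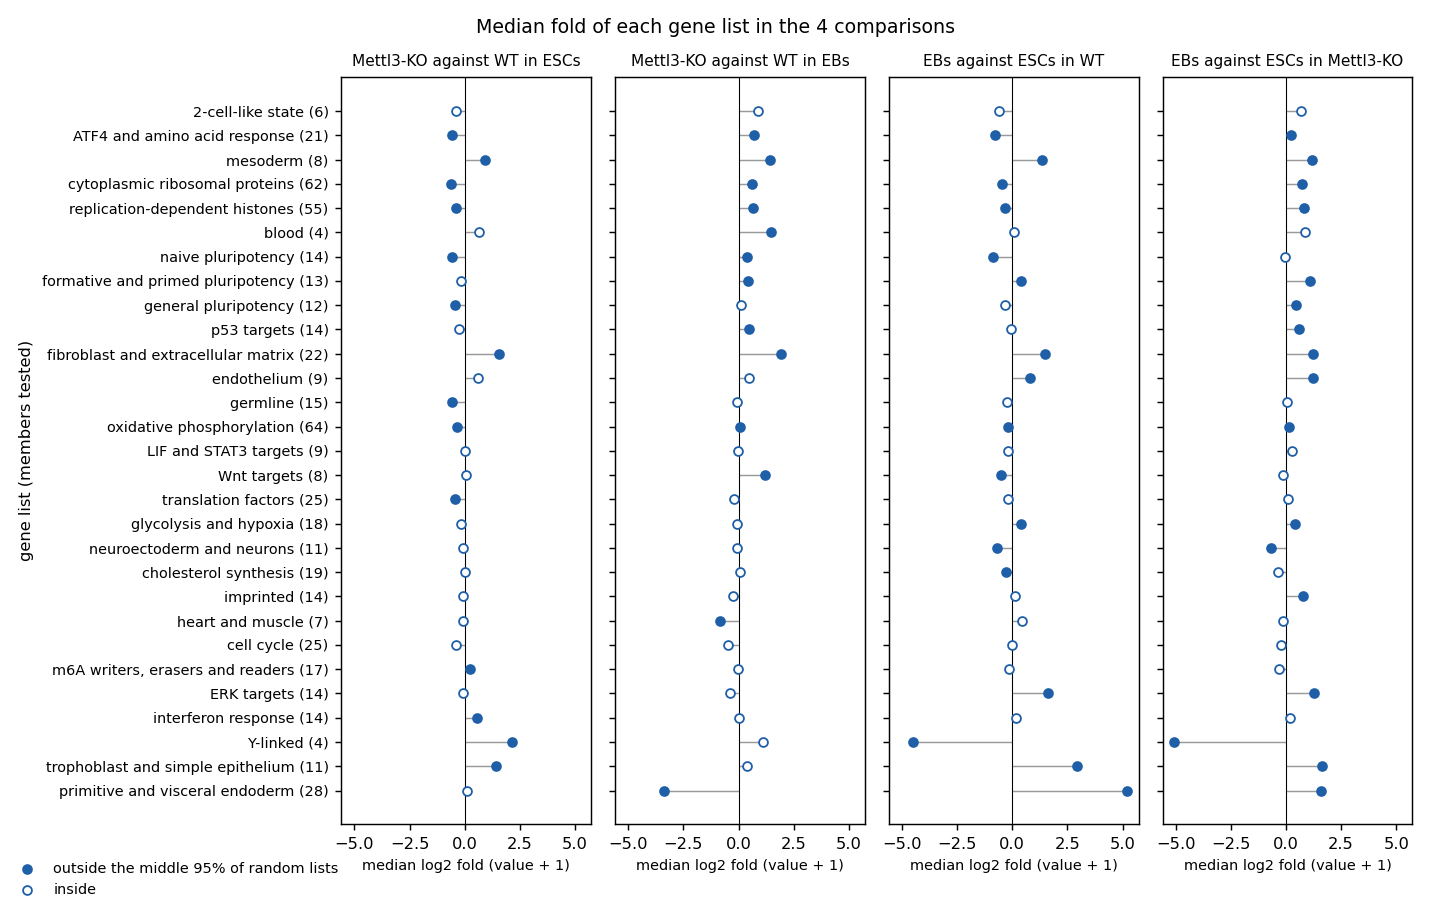
Median log2 fold (value + 1) of each of 29 gene lists in the 4 comparisons of 2 libraries, with the number of members tested in brackets; filled points lie outside the middle 95% of 10000 random lists matched on expression. Endoderm stands at 0.09, −3.37, 5.22 and 1.57 from left to right, and matrix at 1.56, 1.95, 1.498 and 1.24.

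Cell cycle genes had medians of −0.39 and −0.45 for KO against WT in ESCs and EBs, above 342 and 506 of 10000 random lists. Cholesterol synthesis genes had −0.31 and −0.37 for EBs against ESCs in WT and KO, above 170 and 379 random lists. Translation factors had a median of −0.46 in KO ESCs, above 32 random lists. Their median member has 26.1% of its coding sequence copied elsewhere, and the 8 members with under 10% copied had −0.32. In KO EBs all tested translation factors had −0.20, above 4555 random lists, so this value lay near the middle of its random lists. Blood genes, 4 in number, had a median of 1.45 in KO EBs, with 2 at least 2-fold higher and 1 lower. The erythroid factor Nfe2 stood at 6.23 in WT EBs and 128 in KO EBs (20.6-fold, 7.76 to 77.3). LIF and STAT3 targets stayed near 0 in KO ESCs (−0.01) and KO EBs (−0.03), both of which differ in sign between scalings, and the STAT3 feedback inhibitor Socs3 was lower in EBs in WT (2.72-fold, 2.21 to 3.38) and in KO (3.91-fold, 3.19 to 4.84). Neural, germline and imprinted genes had differences of 0.00, 0.36 and −0.07 between the EB changes of KO and WT. The first and last of these differ in sign between scalings, and the imprinted value includes Nckap1. The germline value was 0.05 over the 12 members with under 10% copied.

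Treating genotype and stage as additive gave a count test with 1 residual degree of freedom, whose spread is the interaction itself. For EBs against ESCs edgeR's quasi-likelihood test called 20 genes higher and 5 lower at an adjusted p below 0.05 (smallest adjusted p = 0.0165), among them Fgb, Cubn, Afp, Col15a1, Mgp, Grem1 and Lefty1 upward and Eif2s3y and Ddx3y downward; DESeq2 called 274 and 101. For KO against WT edgeR called 0 genes, with 1556 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0983, while DESeq2 called 251 higher and 71 lower. Adjusted over the list alone, edgeR's test called 23 endoderm genes higher in EBs (4 over all genes), 12 matrix, 9 epithelial and 8 ERK-target genes higher (0 over all genes in each) and 2 naive genes lower (0 over all genes). It also called 4 mesoderm and 4 glycolysis genes higher (0 over all genes in each), 3 formative genes higher (1 over all genes) and 4 Y-linked genes lower (2 over all genes). It called 4 imprinted genes higher and 1 lower, 2 LIF and STAT3 targets and 1 neural gene lower, 2 general pluripotency, 2 blood, 2 endothelial and 1 Wnt-target gene higher, and 1 interferon gene each way (0 over all genes in each), and the same 1 heart and muscle count either way. For KO against WT, adjusted over the list alone, it called 15 matrix, 3 Y-linked, 2 mesoderm, 2 epithelial, 2 Wnt-target and 1 interferon gene higher, 6 endoderm, 2 germline and 1 naive gene lower and 1 ERK target each way, and 0 of any of these over all genes. In the other lists it called 0 genes. No adjustment was made across lists. The test takes the ESC and EB libraries of a genotype as its replicates, so it cannot separate genotype from a difference between cell lines.

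**Figure D4:**
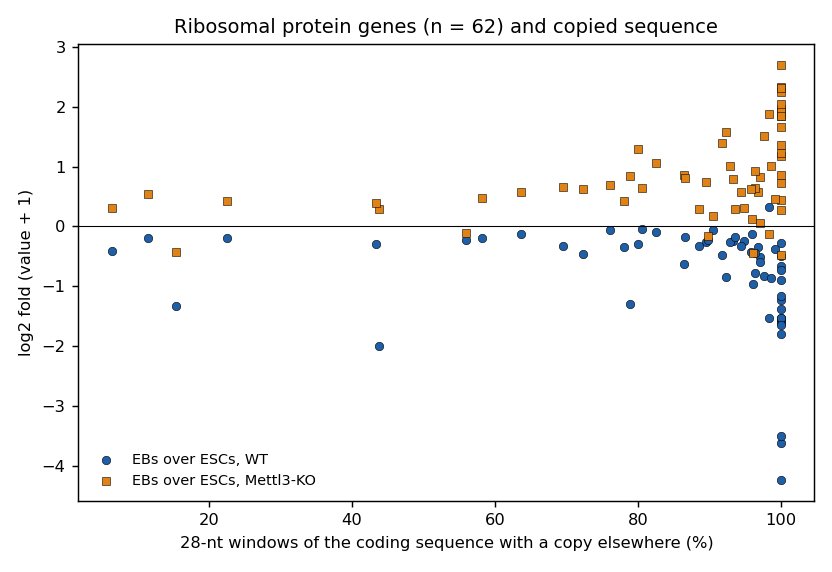
The log2 fold of EBs over ESCs (value + 1) of ribosomal protein genes in WT and KO against the percent of 28-nt windows of the coding sequence that have a copy elsewhere in the genome, 1 point per gene and genotype. Over 62 genes the Spearman coefficient with the percent copied is −0.601 in WT and 0.499 in KO.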

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

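All tests of an explanation reported here were chosen after the result was seen. In 7 gene lists the median EB change had opposite signs in WT and KO cells and differed by at least 0.5 on the log2 scale, a limit set after the data were seen, and these differences were not tested, because each group has 1 library. The ATF4 response stood at −0.76 in WT and 0.23 in KO on the log2 scale, a gap of 0.99. General pluripotency genes stood at −0.33 and 0.45, a gap of 0.78; in WT the 6 with under 10% of windows copied stood at −0.21. The 2-cell-like genes stood at −0.59 and 0.69, a gap of 1.27, with a median of 48.0% of their coding windows copied elsewhere in the genome; the 1 member with under 10% copied stood at 0.11 in WT. The p53 targets stood at −0.08 and 0.60, a gap of 0.68. Heart and muscle genes went the other way, 0.42 in WT and −0.14 in KO, a gap of −0.56, but gene by gene the median difference was −0.18, above 4133 of 10000 random lists. Histones stood at −0.32 and 0.83, a gap of 1.15. Ribosomal protein genes stood at −0.47 and 0.70, a gap of 1.17.

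For the ribosomal protein genes, reads shared with near-identical copies are a candidate explanation of part of the gap. The 19 members with every window copied had a median difference between the EB changes of KO and WT of 2.75, and 19 other genes with every window copied had 1.82, against −0.11 for 8271 other genes with under 10% copied. Over the 62 members the difference had a Spearman coefficient of 0.585 with the percent copied. The 6 members with under 50% copied still had a median of 0.72 and a lowest value of 0.63, which argues against copies as the whole cause. A difference in ribosomal protein translation between genotypes stays open and was not tested.

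The endoderm deficit of KO EBs was set against exchanged labels and shared copies. If the EB libraries alone carried each other's labels, the KO differences of other genes in ESCs and EBs would correlate negatively, provided genotype acted alike at both stages. They had a Spearman coefficient of 0.397. As labelled, however, some lists changed sign between stages, such as naive pluripotency (−0.58 in ESCs and 0.37 in EBs) and the ATF4 response (−0.56 and 0.69). An exchange of labels at both stages would leave the coefficient unchanged. Exchanged labels therefore stay open where that condition fails or where both stages were exchanged. The 2 EB libraries had 4234361 and 4075850 gene reads. Copies are argued against, since no endoderm member had over 0.986% of its windows copied. The day of each EB library, a difference between cell lines and a library from elsewhere stay open, and loss of Mettl3 may contribute only as a hypothesis.

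Of the 4 Y-linked genes tested, 4 in KO and 3 in WT were at least 2-fold lower in EBs than in ESCs; the exception was Kdm5d, at 1.56 in both WT libraries, from 2 reads in ESCs and 1 in EBs. Over all 6 Y-linked genes, Usp9y and Zfy1 included, the WT EB library held 10 reads where the ESC level predicted 287. The KO EB library held 47 where it predicted 1017. At most 4.62% of the predicted reads were found, which argues against depth. Between the ESC libraries, a smaller share of Y-bearing cells in WT would lower each gene alike, but WT stood at 0.737% of KO for Kdm5d (interval 0.0889 to 2.68) and 63.2% for Eif2s3y (55.6 to 71.7), a ratio of 85.8. Different starting lines, loss of all or part of the Y chromosome in culture and libraries of other origin stay open. No biological explanation was tested.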

How the results depend on the processing

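The tests on recovered reads, thinning, and the restrictions to 1 coding sequence, to genes with few copies and to counting intervals were chosen after seeing the data. No paired analysis was possible because each group has 1 library and so no replicate numbers pair libraries; the additive count tests compare genotypes within stages and stages within genotypes. Of the gene counts computed under alternatives 99 stayed within 1.5 times the main count and 23 did not. Of list medians 850 stayed within their error, 17 moved and 3 reversed. That error came from 1000 bootstrap draws of a list's members, so genes stood in as replicates. A median could therefore change sign within its error and count as stayed. Neural medians for KO against WT differed in sign between scalings at both stages. The germline median for EBs against ESCs in WT was −0.24, and 0.26 over the 12 members with under 10% copied. Of named genes 2949 stayed, 170 moved and 1 reversed. Over all settings the Spearman coefficient of the EB changes ranged from 0.237 to 0.319 and that of the KO differences from 0.382 to 0.431.

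With a mean of at least 100, where fewer genes were tested, genes higher and lower numbered 515 and 209 for KO against WT in ESCs, 568 and 397 for EBs against ESCs in WT, 456 and 376 in KO, and 612 and 742 for the difference, and 810 were higher in KO EBs. With no filter, where more genes were tested, they numbered 2090 and 1087 for KO against WT in ESCs, 3100 and 2096 in EBs, 2192 and 1821 for EBs against ESCs in WT, 2096 and 1475 in KO, and 2602 and 2353 for the difference.

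The endothelial medians reversed at a mean of at least 100, to −0.75 in WT and −0.34 in KO for EBs against ESCs, where fewer members were left. The oxidative phosphorylation median for KO against WT in EBs, 0.05, was −0.0296 over genes with under 10% of windows copied; the cause was not tested. The difference for Uty, at 0 reads in WT EBs, was 2.09 with a pseudocount of 1 and −0.39 with 10. Scaling moved the share of higher among all 2-fold genes by under 10 percentage points. An EB library, with 1 read worth 1.56 or 1.49, limits folds of low genes more than an ESC library.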

Other observations

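The counting tests of Y-linked genes and the look at the X chromosome were chosen after the data were seen, as were the genes named here outside the naming rule. X-linked genes were frequent among the genes lowest in KO ESCs: 17 of the 84 genes at least 4-fold lower than in WT, 20.2%, lay on the X chromosome, against 332 of 9670 genes tested, 3.43%. Among the 202 genes at least 4-fold higher 5 did. Of the 17, Taf7l alone is on the germline list. Usp26, a deubiquitinase of testis, stood at 1613 in WT ESCs, 212 in KO ESCs, 1027 in WT EBs and 216 in KO EBs. Taf7l, a germ-cell relative of a general transcription factor subunit, stood at 662, 138, 291 and 403 in the same order, the homeobox gene Rhox13 at 428, 95.5, 68.6 and 158, and Tex13b at 404, 40.0, 57.7 and 58.2. The transketolase-like gene Tktl1 stood at 216, 18.7, 17.1 and 29.9, and the RNA export gene Nxf2 at 122, 17.6, 12.5 and 26.9.

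From ESCs to EBs, 27 of the 276 genes at least 4-fold lower in WT lay on the X chromosome, 9.78%, and 3 of 80 in KO, 3.75%. The X-linked genes as a whole had a median log2 fold of −0.20 in KO ESCs against WT ESCs, and autosomal genes 0.00. In EBs the order was the other way, 0.16 on the X chromosome and −0.08 on autosomes, with 26 of 456 genes at least 4-fold higher in KO (5.70%) and 12 of 249 at least 4-fold lower (4.82%) on the X chromosome. With equal totals the X-linked and autosomal medians were −0.08 and 0.13 in ESCs and 0.28 and 0.04 in EBs, so the sign of the autosomal median in EBs depends on the scaling. These shares and medians were not tested.

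Usp26, Rhox13, Tex13b, Tktl1 and Nxf2 were outside the naming rule, as were Nanog and Col1a1. Nanog, a core factor of naive pluripotency with 27.0% of its coding sequence copied elsewhere, stood at 6105 in WT ESCs and 4514 in KO ESCs. In WT EBs it stood at 3691 and in KO EBs at 4675. The collagen chain Col1a1 stood at 187, 954, 527 and 2733 in the same order of libraries. Across genes, the libraries most alike by Spearman coefficient were the ESC pair, at 0.945, and the pair of lowest likeness was that of the EBs, at 0.878; genes are not independent replicates.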
